A study of Arabidopsis thaliana with 6 samples.

How the data were processed

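Total RNA of Arabidopsis thaliana leaves was labelled with Cy3 and hybridised to 1-colour Agilent arrays, 6 arrays in all, with 2 for each of 3 genotypes, per the labels. Groups and replicate numbers were taken from the sample labels alone. Spot intensity was extracted with Agilent Feature Extraction 11.5, per the submitters' processing notes. The scanner files hold linear spot intensity, background-subtracted by the scanner software in the processed signal, per the file headers. The authors also deposited a spot table and a gene table of log2 values, whose scaling is not given in the sources used here. Each column of the spot table had a Spearman correlation of 1 with the median signal of its own array, and a column median of 7.29. All columns also had the same highest value, 18.6, as quantile normalization would leave. The deposited tables may thus not be a scaling apart from the quantile normalization used as an alternative below. All 20687 genes of the gene table lay within 0.002 of the mean of their spots called present. These log2 tables, deposited by the authors, were used only as an alternative. Probes were named through the deposited table of array elements, which pairs them with TAIR10 loci by BLASTN, per the deposited notes, and symbols came from a RefSeq gene table of TAIR10.1.

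Each array held 45220 spots, of which 1417 control spots and spots with an outlier mark were left out, and spots of a probe were averaged. Of 43603 probes, 37257 matched 1 locus, 15 were named by the accession in the scanner files, 900 matched several loci and were left out, and 5431 had no match and were kept apart. They covered 28324 loci, 7098 of them with several probes, of which the brightest was taken. The log2 of the processed signal was taken and the 75th percentile of each array subtracted. A gene was tested where its probe was well above background on both arrays of at least 1 genotype, which left 20291 loci, 20225 of them without a missing array. The number of arrays limits the precision. Replicate arrays correlated at 0.987 (Col), 0.995 (ore15-1D) and 0.989 (ore15-2).

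Genes were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) on all 6 arrays, which share 1 estimate of the spread with 3 residual and 1.80 prior degrees of freedom. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The series' design text names the arrays of a genotype as independent biological samples, and p-values measure the spread between them. For each mutant both arrays lay on the same slide, so that this spread holds differences between slides only for Col. The 28 gene lists were tested over the 20225 genes without a missing array with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives, where a list had at least 5 measured genes; list medians are over all measured genes. They cover the GRF and GIF genes, G2 and M phase, DNA replication, replication histones, CDK inhibitors and the endocycle, other leaf size regulators, leaf polarity, stomata, trichomes, vasculature, expansins and related enzymes, senescence, photosynthesis, auxin, cytokinin, gibberellin and brassinosteroid, salicylic acid and defence, jasmonate, the clock, cold and abscisic acid, touch, flavonoids, glucosinolates, ribosome biogenesis, PLATZ genes, and shoot meristem, floral and root markers. Counts adjusted over the list alone use the genes of that list only.

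For a probe not well above background on all arrays of the dimmer genotype a lower bound is given as "at least N-fold". It sets the mean of the brighter genotype against the higher of the dim probe's own signal and the lowest signal among probes well above background, per array. Where 1 of 2 arrays measured the probe, this is stated with the fitted value.

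The genotypes, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes ORE15, the 10 genes with the largest rise and the 10 with the largest fall that passed, had non-overlapping arrays and were well above background in the higher genotype, up to 4 members of each list with a call, and up to 5 genes per direction pattern in both mutants. Not all of these are printed. KNAT6, CUC3, the neighbours of ORE15, CHS and the clock genes beyond the 4 with the largest change were named after their values were seen.

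Alternatives were quantile normalization, normexp background correction (offset 50) with the 75th percentile or quantile normalization, no filter or a stricter filter on background, the mean of probes, slide as a fixed or random block, single slides, the replicate number as a block, only the genotypes compared, a trend in the spread, the authors' deposited table, a minimum log2 change of 1, and leaving out each array. Normexp was planned on the mean spot signal, and the median spot signal and the median local background were used, since the scanner files used here hold no mean signal. One slide held 3 arrays, both ore15-1D arrays with Col replicate 1, and the other held Col replicate 2 with both ore15-2 arrays, so that each mutant was also set against the Col array of its own slide.

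The tests were checked on simulated arrays of 20225 genes, with 100 genes changed by a log2 of 1 and 100 by 2. For ore15-1D against Col, 47 of 100 genes changed by a log2 of 1 and 74 of 100 changed by 2 were recovered, with 7 unchanged genes called. For ore15-2 against Col, 57 of 100 and 79 of 100 were recovered, with 5 unchanged genes called. These simulated arrays held independent noise and no slide effect, and far fewer genes changed than were called in ore15-1D. The rates need not carry over to the measured arrays. Shared Col arrays were treated with 100 simulations of unchanged groups, and for overlaps of called genes with 20 in which lists of the same length were taken by rank.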

Results

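RNA levels were measured in young rosette leaves of 3 Arabidopsis thaliana genotypes on 1-colour Agilent arrays, with 2 independent biological samples, each on its own array, per genotype. The genotypes were Col, the wild type, and plants carrying the ore15-1D or the ore15-2 allele of ORE15 (AT1G31040). ORE15 encodes a plant-specific zinc-binding protein of the PLATZ family. ore15-1D is a dominant allele and ore15-2 a loss-of-function allele, as the names and the known use of these lines give them. Leaves were taken 4 days after emergence from plants grown for 13 days on soil under 16 h light and 8 h dark, at 5 h after light-on. Between 67.8% and 73.0% of the probe spots of an array were well above background, no spot was saturated, and the 75th percentile of the signal ranged from 747 to 1338. It was 1249 and 1338 on the ore15-1D arrays, 927 and 859 in Col, and 809 and 747 in ore15-2, without overlap between genotypes. The number of arrays limits the precision of every value below. Both ore15-1D arrays and Col replicate 1 lay on slide 1, and Col replicate 2 and both ore15-2 arrays on slide 2. Changes are log2 differences between group means with the standard error (SE) of the limma fit, n = 2 arrays per group, and a gene is said to have risen, fallen or changed where its two-sided limma test gave an adjusted p below 0.05.

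ORE15 itself was read first. Its probe, at chromosome 1 positions 11069800 to 11069859 of TAIR10, lies in the AT1G31040 transcript. Whether it lies in the part of the gene that the ore15-2 allele affects is not given in the sources used here, so its value in ore15-2 does not check that genotype. In Col its log2 signal relative to the 75th percentile of the array was -4.84 ± 0.08 (SD, n = 2), and in ore15-1D it was 2.70 ± 0.06 (SD, n = 2). The rise in ore15-1D was 7.55 ± 0.67 (SE; adjusted p = 0.00545), and it was 4.299 and did not pass after normexp background correction with the local background (adjusted p = 0.371). After normexp with quantile normalization it was 5.18 and passed (adjusted p = 8.42e-06). In ore15-2 the level was -7.41 ± 1.46 (SD, n = 2), and the probe was well above background on replicate 1 (-6.38) and not on replicate 2 (-8.44). The change of -2.56 ± 0.67 in ore15-2 missed the threshold over all genes (adjusted p = 0.125). It was -1.53 without ore15-2 replicate 2 (adjusted p = 0.0761), and without ore15-2 replicate 1 only a bound remained, at least 2.75-fold lower than in Col (adjusted p = 0.036 in the fit). It was -0.34 after normexp with quantile normalization and did not pass (adjusted p = 0.0694). Of the 10 other tested loci from AT1G30960 to AT1G31130 around ORE15, 5 changed in ore15-1D, near the share of 40.6% over all genes. AT1G31100, a transposable element gene, fell by 1.78 (SE 0.39), and AT1G30960, AT1G30970, AT1G31010 and AT1G31070 rose by 0.43 to 0.71. The nearest tested loci on either side, AT1G31020 and AT1G31050, gave 0.20 ± 0.10 and -0.11 ± 0.26 in ore15-1D and did not pass. In ore15-2, AT1G30970 rose by 0.82 ± 0.10 and AT1G31020 by 0.93 ± 0.10. With slide as a block 3 of these loci passed in ore15-1D, without either ore15-1D array 0 did by limma, and without either Col array 3 did.

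**Figure D1:**
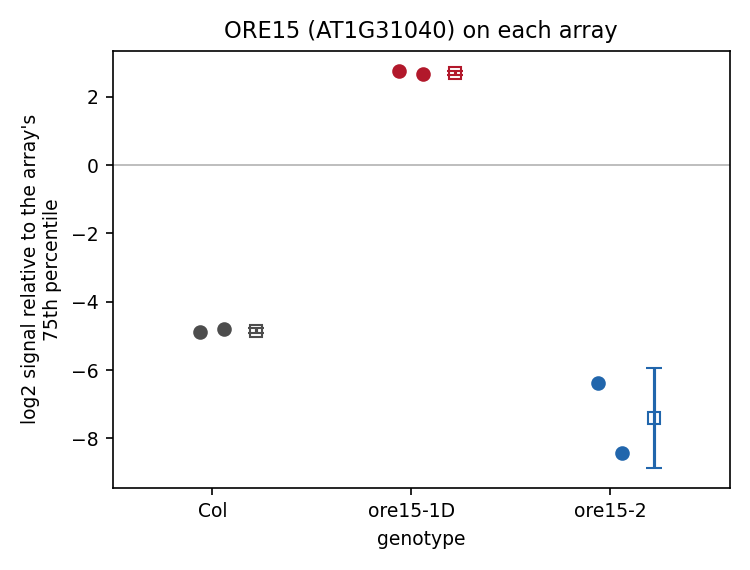
ORE15 on each array. Filled circles are single arrays and open squares with bars are the mean ± SD of the 2 arrays of a genotype, as log2 signal relative to the 75th percentile of the array (grey line at 0). The ore15-1D arrays lie at a mean of 2.70, Col at -4.84 and ore15-2 at -7.41, where the probe was well above background on 1 of 2 arrays.

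The comparison of ore15-1D with Col asks which genes differ in leaves with a raised ORE15 level. In ore15-1D leaves 22 of 25 DNA replication, 11 of 13 histone, 6 of 29 G2 and M phase and 6 of 12 growth-regulating factor (GRF) and GIF co-activator genes rose. Over all genes 3771 of 20287 rose and 4469 fell, so the G2 and M phase count is near the share over all genes. All 51 photosynthesis, 19 of 20 glucosinolate, 16 of 26 senescence and 12 of 22 defence genes fell, while 2 defence genes rose. Each of these lists passed by camera with its preset correlation and none with an estimated one (adjusted p = 0.384 with an estimated correlation for senescence and adjusted p = 0.562 with an estimated correlation for the others). Among the largest rises after ORE15 were AT1G12160, a flavin-binding monooxygenase gene (at least 19.9-fold), EDA12 (4.45 ± 0.30, well above background on 1 of 2 Col arrays) and AT1G67790, of unknown function (3.89 ± 0.12). ENDO3, an endonuclease gene, rose at least 10.8-fold, COPT3, a copper transporter gene, at least 4.59-fold, and CLE40, for a signalling peptide, by 3.29 ± 0.65 (well above background on 1 of 2 Col arrays). The largest falls included AT4G33467, of unknown function (at least 88.4-fold), and ASN1, the dark-inducible asparagine synthetase gene (-7.55 ± 0.46, well above background on 1 of 2 ore15-1D arrays). AT2G20670 fell by 5.82 (SE 0.42), with BT2 at -5.39 ± 0.85 and the defence-related PCC1 at -5.49 ± 1.27. MIOX2, a myo-inositol oxygenase gene, fell at least 9.82-fold and the receptor kinase gene CRK12 at least 10.8-fold.

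In all, 8240 of 20287 genes (40.6%) changed in ore15-1D, 3771 higher and 4469 lower, and 2446 of them changed by a log2 difference of at least 1, with 546 higher and 1900 lower. The split depended on scaling, with 4693 higher and 3683 lower after quantile normalization, 4753 and 3561 after normexp with quantile normalization, and 4654 and 3375 in the authors' deposited table. With slide as a block 3885 genes passed, and 0 did by limma after normexp correction with the local background (2255 at an unadjusted p below 0.05, with the median of all genes moved to -0.25). Without either ore15-1D array or either Col array fewer genes passed, each fit having a single array left in that genotype. Slide 1 alone also holds a single Col array, without a spread of its own, so no count is given for it.

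The growth-regulating factors (GRF) and their GIF co-activators promote cell proliferation in leaves. Of the 12 measured, 6 rose in ore15-1D and 6 did so adjusted over the list alone. GRF6 rose by 2.37 ± 0.32, GRF4 by 1.48 ± 0.36 and GRF1 by 1.41 ± 0.24, and GRF8 rose at least 1.58-fold. The list's median was 1.298 (camera, adjusted p = 0.00661; adjusted p = 0.562 with an estimated correlation), and 1.04 against Col replicate 1 of the same slide. DNA replication and G1 to S genes rose in 22 of 25 cases (22 adjusted over the list alone), with a median of 0.83 (adjusted p = 8.91e-08; adjusted p = 0.562 with an estimated correlation) and 0.87 on the same slide. They included PCNA2, the sliding clamp of DNA polymerase (1.296 ± 0.17), the D-type cyclin CYCD3;2 (1.17 ± 0.12) and MCM2, of the replicative helicase (0.99 ± 0.14). Of 29 genes of G2 and M phase, 6 rose (4 adjusted over the list alone), among them CYCB2;3 (1.84 ± 0.35), CDKB1;2 (1.32 ± 0.28) and the cytokinesis kinesin TETRASPORE (1.24 ± 0.15). Their median was 0.89 (adjusted p = 2.91e-05; adjusted p = 0.562 with an estimated correlation), against 0.66 on the same slide. Replication histone genes, which are near-identical copies whose probes can share signal, rose in 11 of 13 cases (12 adjusted over the list alone), with HTR13 at 1.06 ± 0.17 and a median of 0.85 (adjusted p = 2.29e-04; adjusted p = 0.562 with an estimated correlation; 0.80 on the same slide). Ribosome biogenesis genes rose in 4 of 13 cases (4 adjusted over the list alone), with NAP57 at 0.74 ± 0.18 and BRX1-2 at 0.69 ± 0.16. Their median was 0.42 (adjusted p = 0.0109; adjusted p = 0.562 with an estimated correlation), 0.63 on the same slide and 0.24 without Col replicate 1, where the list no longer passed (adjusted p = 0.0776).

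Beside these groups, markers of other tissues gave the following values in ore15-1D. Of 10 shoot meristem and boundary markers 3 were measured, where the receptor kinase gene CLV1 fell by 0.78 (SE 0.12; 1 lower adjusted over the list alone) and KNAT6 and CUC3 gave 0.33 and 0.16 and did not pass. Among 4 measured floral markers FUL rose by 2.46 ± 0.12 and SEP3 by 1.01 ± 0.23 (2 adjusted over the list alone). Of 7 root markers 3 fell, the nitrate transporter gene NRT2.1 at least 15.5-fold, IRT1 at least 2.43-fold and PIP2;4, an aquaporin gene, with a change of -0.62 ± 0.12, and 1 was higher and 3 lower adjusted over the list alone (camera, adjusted p = 0.0683). The vascular list fell as a set, with 5 of 9 genes lower (6 lower and 1 higher adjusted over the list alone), among them SUC2, the phloem sucrose transporter gene (-1.28 ± 0.25), and XCP2 of the xylem (-0.81 ± 0.10). Its median was -0.39 (adjusted p = 0.019; adjusted p = 0.562 with an estimated correlation) and -0.32 on the same slide, and the set did not pass without a filter on background (adjusted p = 0.0671).

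All 51 measured nuclear genes of the photosystems and the Calvin cycle fell in ore15-1D, over all genes and adjusted over the list alone. LHCB4.3 fell by 1.61 (SE 0.34), with LHCB2.4 at -1.26 ± 0.15 and RBCS1B, a small subunit of Rubisco, at -1.12 ± 0.14. The median was -0.71 (camera, adjusted p = 6.86e-14; adjusted p = 0.562 with an estimated correlation) and -0.67 against Col replicate 1. It was -0.20 after quantile normalization, and -0.26 after normexp with the local background, where the list did not pass (adjusted p = 0.214). Glucosinolate synthesis genes fell in 19 of 20 cases (20 adjusted over the list alone), led by CYP79B2 (-4.82 ± 0.16) and CYP79B3 (-2.75 ± 0.19), which act at the entry of the indole branch, and by their regulator MYB51 (-2.61 ± 0.43). The median was -1.32 (adjusted p = 1.34e-07; adjusted p = 0.562 with an estimated correlation) and -1.28 on the same slide. Of 26 senescence genes 16 fell, and 17 were lower and 1 higher adjusted over the list alone. SEN1 fell by 3.63 (SE 0.37), with DIN10 at -2.37 ± 0.36 and WRKY22 at -2.05 ± 0.25, and the list's median was -0.78 (adjusted p = 2.91e-05; adjusted p = 0.384 with an estimated correlation), against -0.82 on the same slide.

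Genes of cell expansion and of several hormones were also lower in ore15-1D. Of 31 expansin and xyloglucan endotransglucosylase genes 11 fell and 2 rose (12 and 2 adjusted over the list alone), with XTH7 at -3.67 ± 0.34, EXPA11 at -2.15 ± 0.33 and XTH33 at least 5.10-fold lower. Their median was -0.60 (adjusted p = 0.0128; adjusted p = 0.562 with an estimated correlation) and -0.48 on the same slide, and the set did not pass without a filter on background (adjusted p = 0.0846). Of 16 gibberellin and brassinosteroid genes 9 fell and 1 rose, also adjusted over the list alone, among them GASA1 (-4.31 ± 0.70), GASA6 (-2.86 ± 0.12) and DWF4 of brassinosteroid synthesis (-1.62 ± 0.16). Their median was -0.91 (adjusted p = 0.00857; adjusted p = 0.562 with an estimated correlation), and -0.57 on the same slide. Salicylic acid and defence genes fell in 12 of 22 cases and rose in 2 (13 and 2 adjusted over the list alone), with SARD1 at -4.21 ± 0.39 (well above background on 1 of 2 ore15-1D arrays) and ACD6 at -3.07 ± 0.49. The median was -0.94 (adjusted p = 0.00212; adjusted p = 0.562 with an estimated correlation) and -0.72 on the same slide. Of 24 jasmonate genes 6 fell, near the share over all genes (4469 of 20287), and 1 rose (5 and 1 adjusted over the list alone). The falls were led by the synthesis genes AOC1 (-2.20 ± 0.14) and AOS (-1.64 ± 0.20). The jasmonate list's median was -0.78 (camera, adjusted p = 0.00857, and adjusted p = 0.562 with an estimated correlation) and -0.71 on the same slide. The set did not pass without a filter on background (adjusted p = 0.062). Touch and rapid stress genes fell in 5 of 16 cases (3 adjusted over the list alone), with ERF1A at -1.77 ± 0.40 and the calmodulin-like TCH3 at -1.51 ± 0.29. Their median was -1.35 (adjusted p = 0.00255; adjusted p = 0.562 with an estimated correlation) and -1.45 on the same slide.

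The other lists did not pass as sets in ore15-1D with all arrays and the planned scaling. The cold and abscisic acid list passed with slide as a block and without Col replicate 2 (median -0.63, adjusted p = 0.0223 in each), the root list without ore15-1D replicate 1 (-0.74, adjusted p = 0.0343), the cytokinin list without Col replicate 1 (-0.40, adjusted p = 0.0198) and the auxin list after normexp with the local background (-0.63, adjusted p = 0.0447). With fry, which tests whether a set moves one way on balance, the GRF and GIF (adjusted p = 0.0831), G2 and M phase (0.119), histone (0.0556), ribosome biogenesis (0.131) and touch (0.0972) lists did not pass in ore15-1D, while the clock and root lists did (0.00976 each). In the flavonoid list 7 of 16 genes fell and 3 rose (9 and 4 adjusted over the list alone; camera, adjusted p = 0.309), with UGT79B1 at -2.78 ± 0.28 and the regulator PAP1 at -2.08 ± 0.22. In the clock list 8 of 22 genes fell and 2 rose, also adjusted over the list alone (adjusted p = 0.16), with ELF4 at -2.47 ± 0.18 and PRR5 at -1.58 ± 0.23. The type-A response regulators ARR6 (-2.35 ± 0.48) and ARR5 (-1.83 ± 0.38) were among 4 of 17 cytokinin genes that fell (4 adjusted over the list alone; adjusted p = 0.149). Among CDK inhibitors and endocycle regulators 4 of 13 rose and 3 fell (5 and 3 adjusted over the list alone; adjusted p = 0.224), with KRP1 at -1.18 ± 0.13 and SMR1 at -1.21 ± 0.21. Of 19 further leaf size regulators 4 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.309), with SPT at 1.60 ± 0.29, ANT at 0.93 ± 0.26 and ROT3 at -1.61 ± 0.23. Leaf polarity genes rose in 2 and fell in 3 of 11 cases, also adjusted over the list alone (adjusted p = 0.787), with YAB5 at -1.25 ± 0.10. In the stomatal list 1 of 16 rose and 4 fell (1 and 3 adjusted over the list alone; adjusted p = 0.983), with ER at 1.06 ± 0.16 and FAMA at -0.83 ± 0.14. The trichome regulator GL3 rose at least 2.26-fold and GL2 by 0.53 ± 0.15 among 9 genes (1 adjusted over the list alone; adjusted p = 0.199). Auxin response genes rose in 3 and fell in 3 of 24 cases (1 and 2 adjusted over the list alone; adjusted p = 0.802), with IAA6 at -1.91 ± 0.37. Of 15 cold and abscisic acid genes 3 fell (3 adjusted over the list alone; adjusted p = 0.21), with COR414-TM1 at -1.37 ± 0.21. Among 7 measured PLATZ genes ORE15 rose and 3 fell (1 and 4 adjusted over the list alone), with AT1G32700 at -1.07 ± 0.11. That list's median was -0.57 and its mean 0.62, owing to ORE15 (adjusted p = 0.253).

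**Figure D2:**
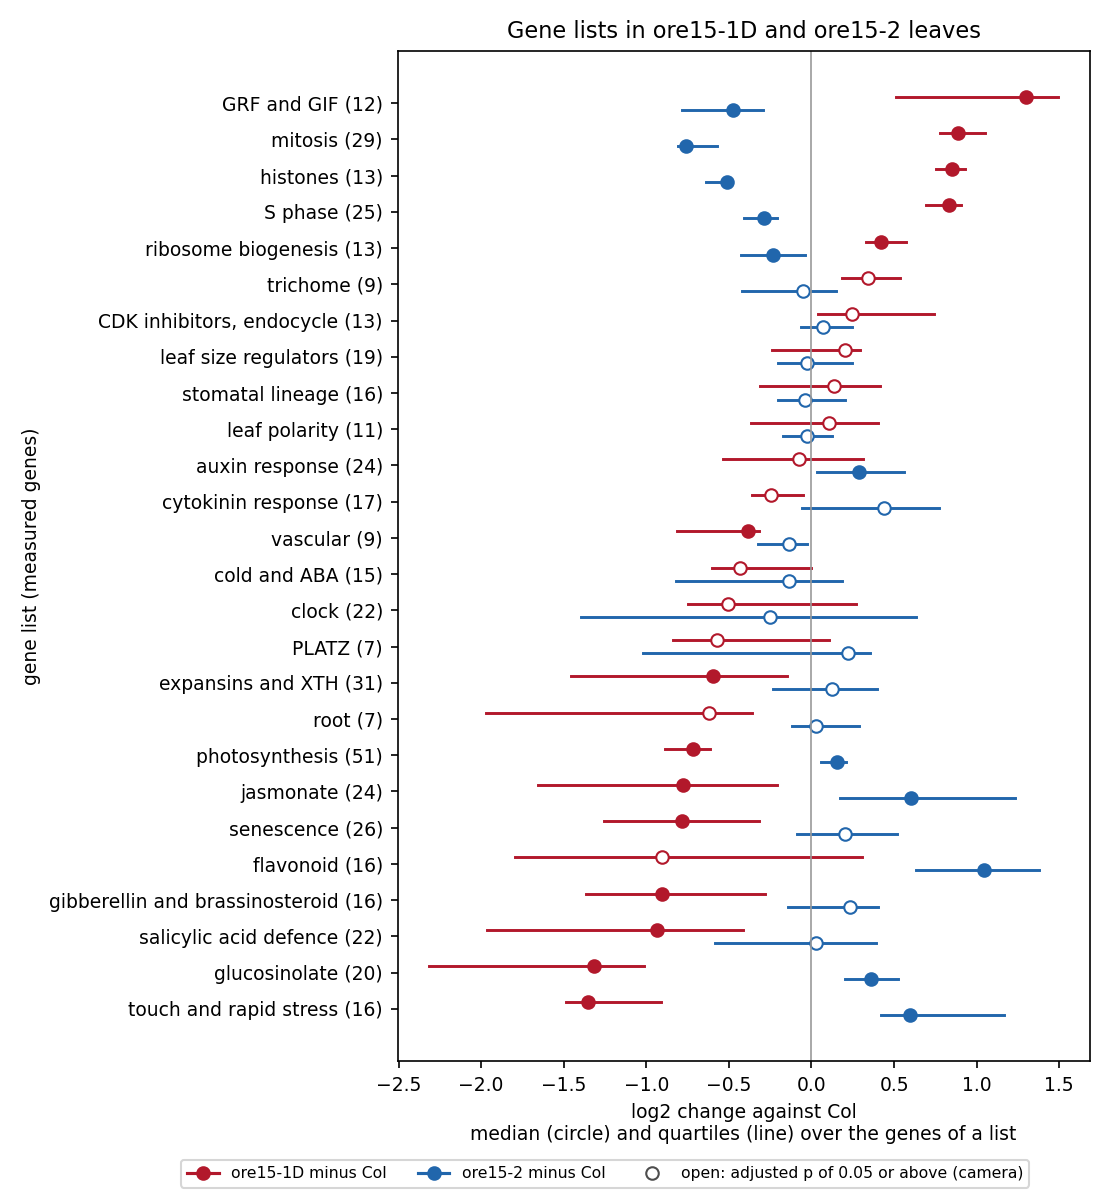
Gene lists in both mutants. Circles are the median log2 change against Col over the measured genes of a list (number in brackets), lines span the quartiles of those genes, and filled circles mark lists with a camera adjusted p below 0.05. The GRF and GIF list lies at 1.298 in ore15-1D and -0.48 in ore15-2, and the photosynthesis list at -0.71 and 0.16, the latter -0.013 after quantile normalization.

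The comparison of ore15-2 with Col asks which genes differ where ORE15 function is lost. In ore15-2 leaves 8 of 16 flavonoid genes rose (camera, adjusted p = 2.19e-09; adjusted p = 0.752 with an estimated correlation). Of the clock genes, 4 of 9 that peak around dawn rose and 8 of 10 that peak later in the day fell, and these parts of the clock list were not tested as sets. Among the largest rises were AT2G15555 (3.44 ± 0.55, well above background on 1 of 2 Col arrays), AT2G41640, a glycosyltransferase gene (3.43 ± 0.28), AT2G16367, a defensin-like gene (3.36 ± 0.38), and DFR, dihydroflavonol reductase of the anthocyanin branch (2.96 ± 0.17). AT5G35375 rose at least 17.0-fold, AT5G18037 at least 6.22-fold and RGP3 at least 5.70-fold. The largest falls included AT5G23240, a DNAJ-domain gene (-5.52 ± 0.38, well above background on 1 of 2 ore15-2 arrays), AT4G33467 (-4.20 ± 0.64), AT1G07050, a CCT-motif gene (-3.56 ± 0.25), and AT2G33830, a dormancy-associated gene (-3.24 ± 0.18). COR27, an evening gene that also responds to cold, fell at least 6.01-fold, and MIOX2 at least 7.01-fold.

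In all, 756 of 20285 genes (3.73%) changed in ore15-2, 438 higher and 318 lower, with 4520 at an unadjusted p below 0.05. The ore15-1D arrays share the estimate of spread, and by limma the count was 0 in the ore15-2 and Col arrays alone and without either ore15-1D array (3372 at an unadjusted p below 0.05 in each). With slide as a block it was 1 by limma (3612 at an unadjusted p below 0.05). The count and its balance of higher and lower genes also depended on which ore15-2 or Col array was left out. Those fits and slide 2 alone hold a single array in 1 genotype, without a spread of its own, so no count is given here. The count was also 0 by limma without a filter on background (4349 at an unadjusted p below 0.05) and 0 after normexp with the local background (725, with the median of all genes moved to -0.22). It was 1199 after normexp with quantile normalization and 1154 with a trend in the spread.

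Of 16 measured flavonoid and anthocyanin genes 8 rose in ore15-2 (12 adjusted over the list alone). DFR, LDOX (2.50 ± 0.23) and UGT79B1 (1.82 ± 0.28) act in the anthocyanin branch, and F3'H (1.27 ± 0.17) and CHS, chalcone synthase (1.11 ± 0.17), act before it. The list's median was 1.04 (camera, adjusted p = 2.19e-09; adjusted p = 0.752 with an estimated correlation) and 0.98 against Col replicate 2 of the same slide. Clock genes changed in both directions, 4 of 22 higher and 8 lower (9 and 10 adjusted over the list alone), so that the set did not pass as shifted one way (median -0.25, adjusted p = 0.307). The dawn genes LHY (2.53 ± 0.33), CCA1 (1.81 ± 0.24), RVE8 (1.08 ± 0.14) and LNK2 (1.00 ± 0.10) rose. PRR5 (-3.40 ± 0.23), CCR2 (-2.74 ± 0.37), ELF4 (-2.31 ± 0.18), LUX (-1.90 ± 0.23), FKF1 (-1.43 ± 0.20), GI (-1.28 ± 0.15), TOC1 (-1.10 ± 0.17) and ELF3 (-0.70 ± 0.11), which peak later in the day, fell. With fry the clock list (adjusted p = 0.0421) and the flavonoid list (adjusted p = 0.0358) passed in ore15-2 and no other list did, the next lowest being 0.141. On the same slide LHY gave 2.28, CCA1 1.62, PRR5 -3.45 and CCR2 -2.68, which did not pass with slide as a block, and RVE8 gave -1.05 after normexp with the local background.

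**Figure D3:**
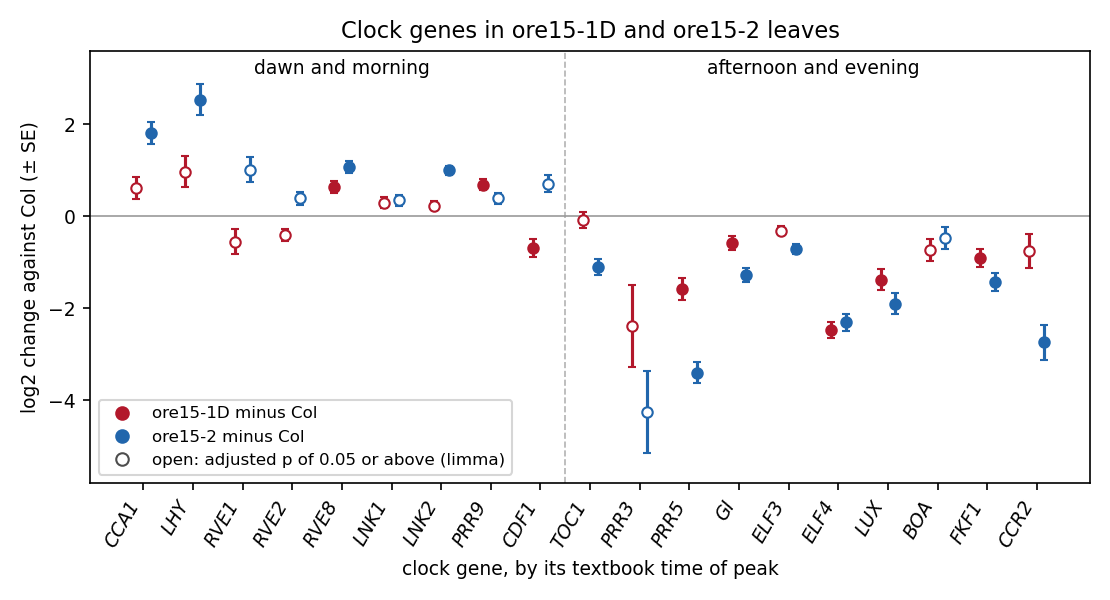
Clock genes in both mutants. Points are log2 changes against Col with SE bars, filled where the limma adjusted p is below 0.05, for genes grouped by their textbook time of peak. In ore15-2, LHY lies at 2.53 and PRR5 at -3.40, against 0.97 and -1.58 in ore15-1D.

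Lists of proliferation genes were lower as sets in ore15-2 only by camera with its preset correlation of 0.01, and none of their members passed alone. The correlation estimated between members was 0.772 to 0.965, so they are far from independent. None of these lists passed with fry (adjusted p from 0.339 to 0.505). For G2 and M phase genes the median was -0.76 (camera, adjusted p = 1.07e-05; adjusted p = 0.752 with an estimated correlation) and -0.53 on the same slide, and 0 of 29 members passed by limma, over all genes or adjusted over the list alone (3 at an unadjusted p below 0.05). KNOLLE gave -1.05 ± 0.37 and CDKB2;1 -0.70 ± 0.24. For the histone list the median was -0.51 (adjusted p = 8.68e-05; adjusted p = 0.752 with an estimated correlation) and -0.49 on the same slide, with 0 of 13 members passing by limma, also adjusted over the list alone (8 unadjusted). It was -0.085 after normexp with the local background. For DNA replication genes it was -0.29 (adjusted p = 1.79e-04; adjusted p = 0.752 with an estimated correlation) and -0.30 on the same slide, with 0 of 25 by limma, also adjusted over the list alone (3 unadjusted). The set did not pass without ore15-2 replicate 2 (median -0.095, adjusted p = 0.0611) or after normexp with the local background (adjusted p = 0.207). For the GRF and GIF genes it was -0.48 (adjusted p = 0.0174; adjusted p = 0.752 with an estimated correlation) and 0 of 12 passed by limma, also adjusted over the list alone (1 unadjusted), with GRF1 at -0.75 ± 0.24 and GRF9 at -1.20 ± 0.59. That set did not pass with slide as a block (median -0.42, adjusted p = 0.29) or without ore15-2 replicate 2 (median -0.083, adjusted p = 0.368). For ribosome biogenesis it was -0.23 (adjusted p = 0.0357; adjusted p = 0.752 with an estimated correlation), -0.47 on the same slide and 0.013 after normexp with the local background, with 0 of 13 by limma, also adjusted over the list alone (2 unadjusted). It did not pass without Col replicate 2 (-0.067, adjusted p = 0.676) or without ore15-2 replicate 2 (-0.21, adjusted p = 0.224).

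Jasmonate genes were higher as a set in ore15-2, with a median of 0.60 (camera, adjusted p = 1.41e-04; adjusted p = 0.752 with an estimated correlation) and 0.47 on the same slide. None of 24 passed over all genes (0 by limma, 11 at an unadjusted p below 0.05) and 9 were higher adjusted over the list alone, with LOX3 at 1.86 ± 0.33 and AOC1 at 0.82 ± 0.14. Touch and rapid stress genes had a median of 0.60 (adjusted p = 0.012; adjusted p = 0.752 with an estimated correlation) and 0.75 on the same slide, with 0 of 16 by limma, also adjusted over the list alone (5 unadjusted). They did not pass without Col replicate 2 (adjusted p = 0.0722) or without ore15-2 replicate 1 (adjusted p = 0.144). Glucosinolate genes had a median of 0.36 (adjusted p = 0.00204; adjusted p = 0.752 with an estimated correlation) and 0.25 on the same slide, with 0 of 20 by limma (5 unadjusted) and 2 higher adjusted over the list alone, and CYP79B3 at 0.96 ± 0.19. Without ore15-2 replicate 2 they did not pass (median 0.12, adjusted p = 0.368). Auxin response genes had a median of 0.29 (adjusted p = 0.0357; adjusted p = 0.752 with an estimated correlation), 0.27 with slide as a block where the set did not pass (adjusted p = 0.121), and 0 of 24 by limma, also adjusted over the list alone (4 unadjusted). They did not pass without Col replicate 2 (adjusted p = 0.0738), without ore15-2 replicate 2 (adjusted p = 0.086) or after quantile normalization (adjusted p = 0.0677), and the median was -0.36 after normexp with the local background. Photosynthesis genes had a median of 0.16 (adjusted p = 0.00191; adjusted p = 0.766 with an estimated correlation), with 0 of 51 by limma, also adjusted over the list alone (6 unadjusted). That direction was lost after quantile normalization (-0.013), and the set did not pass with slide as a block (0.084, adjusted p = 0.0586) or without ore15-2 replicate 2 (0.028, adjusted p = 0.411).

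In the lists that did not pass in ore15-2, other than the clock list with 12 of 22, at most 2 genes changed. EXPA10 rose by 1.22 ± 0.09 among 31 cell wall genes (1 adjusted over the list alone), TCP24 by 0.86 ± 0.09 among 19 leaf size regulators (1 adjusted over the list alone), and KRP6 by 0.76 ± 0.09 among 13 CDK inhibitor and endocycle genes (1 adjusted over the list alone). DIN10 fell by 2.36 (SE 0.36) among 26 senescence genes (4 higher and 4 lower adjusted over the list alone). NIMIN1 fell by 0.94 (SE 0.15) among 22 defence genes (1 adjusted over the list alone). LTI30 fell by 0.64 (SE 0.10) among 15 cold and abscisic acid genes (1 higher and 4 lower adjusted over the list alone), and GID1A fell by 0.52 (SE 0.08) among 16 gibberellin and brassinosteroid genes (1 higher and 1 lower adjusted over the list alone). Among the 4 floral markers PI rose by 1.88 ± 0.20 and SEP3 fell by 1.69 (SE 0.23), and 1 was higher and 2 lower adjusted over the list alone. By limma 0 genes passed among 9 vascular (3 lower adjusted over the list alone, 3 unadjusted), 17 cytokinin (2 higher, 5 unadjusted) and 7 PLATZ genes (2 higher and 1 lower, 3 unadjusted). Likewise 0 passed, also adjusted over the list alone, among 11 leaf polarity (2 unadjusted), 16 stomatal (2), 9 trichome (1), 7 root (1) and 3 meristem genes (1). The camera adjusted p was 0.076 for the vascular list, 0.0934 for cytokinin, and between 0.307 and 0.908 for the other tested lists. The vascular list passed with slide as a block and without Col replicate 1 (median -0.24, adjusted p = 0.035 in each) and without ore15-2 replicate 2 (-0.17, adjusted p = 0.0157). Without Col replicate 2 the cytokinin list (0.69, adjusted p = 0.00924) and the cold and abscisic acid list (-0.33, adjusted p = 0.00982) passed.

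The direct comparison of ore15-1D with ore15-2 sets the dominant against the loss-of-function allele. ORE15 was higher in ore15-1D by 10.11 ± 0.67 (adjusted p = 0.00246), well above background on 1 of 2 ore15-2 arrays, and by 10.22 with slide as a block, where it did not pass (adjusted p = 0.0533). After normexp it was 6.09 with the local background and the 75th percentile, which did not pass (adjusted p = 0.21), and 5.52 with quantile normalization (adjusted p = 5.64e-06). All 25 DNA replication, all 13 histone and 28 of 29 G2 and M phase genes were higher in ore15-1D than in ore15-2. All 51 photosynthesis, all 20 glucosinolate and 13 of 16 flavonoid genes were lower, and 2 flavonoid genes were higher. These lists passed by camera (adjusted p = 0.559 with an estimated correlation for each). AT5G23240 was higher by 4.46 ± 0.38 and the trichome regulator GL1 by 4.09 ± 0.99, each well above background on 1 of 2 ore15-2 arrays, and AT1G67790 by 3.87 ± 0.12. XTH31 was lower by a log2 change of -7.49 ± 1.04 (well above background on 1 of 2 ore15-1D arrays), AT2G16367 by -6.84 ± 0.38 and AT2G32870, a TRAF-like gene, at least 53.3-fold. Of 20287 genes 11295 differed, 5292 higher and 6003 lower in ore15-1D, and 4333 differed by a log2 change of at least 1. The balance turned with scaling, to 6240 higher and 5004 lower after quantile normalization, 6121 and 4895 after normexp with quantile normalization, and 6160 and 4684 in the authors' deposited table. The arrays of these genotypes lay on different slides and are linked only through Col, and with slide as a block 0 genes passed by limma (7508 at an unadjusted p below 0.05), as did 0 after normexp with the local background (2829). There were 5026 without ore15-1D replicate 1 and 4769 without ore15-1D replicate 2, and normexp without the local background, added after the data were seen, gave 12894 with the median of all genes moved to -0.12.

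All 25 DNA replication genes (median 1.17) and all 13 histone genes (median 1.43) were higher in ore15-1D than in ore15-2, over all genes and adjusted over the list alone. So were 28 of 29 genes of G2 and M phase (29 adjusted over the list alone; median 1.61), 9 of 12 GRF and GIF genes (9; median 2.03) and 7 of 13 ribosome biogenesis genes (8; median 0.80). GRF5 (AT3G13960) was higher by 3.03 ± 0.91, GRF6 by 2.74 ± 0.32, CYCB2;3 by 2.15 ± 0.35, AUR3 by 2.00 ± 0.39 and PCNA2 by 1.77 ± 0.17. These 5 lists passed with camera adjusted p from 1.43e-08 to 0.00237 (adjusted p = 0.559 with an estimated correlation for each). All 51 photosynthesis genes (median -0.84) and all 20 glucosinolate genes (median -1.67) were lower, over all genes and adjusted over the list alone. Lower too were 13 of 16 flavonoid genes, with 2 higher (13 and 2 adjusted over the list alone; median -2.36), 19 of 26 senescence genes (19; median -0.83), 18 of 24 jasmonate genes with 1 higher (20 and 1; median -1.27) and 13 of 16 touch and rapid stress genes (15; median -2.03). DFR was at -4.70 ± 0.17, CYP79B2 at -5.44 ± 0.16, JAZ7 at -5.15 ± 1.05, ZAT10 at -2.89 ± 0.44 and the senescence regulator NAP at -2.74 ± 0.25. Expansin and related genes (16 lower and 2 higher; 16 and 2 adjusted over the list alone; median -1.01), gibberellin and brassinosteroid genes (9 and 2; 11 and 2; -1.37), defence genes (13 and 2; 14 and 2; -1.03) and cytokinin genes (7 and 1; 7 and 1; -0.63) were lower as sets. These 10 lists passed with camera adjusted p from 6.67e-13 to 0.0364. The senescence list had adjusted p = 0.484 with an estimated correlation and the others adjusted p = 0.559 with an estimated correlation. After quantile normalization all 15 lists passed by camera with its preset correlation. The photosynthesis list then lay against Col at -0.20 in ore15-1D and -0.013 in ore15-2, against -0.71 and 0.16 with the planned scaling. The size of its difference between the mutants may therefore depend on the scaling. Without a filter on background the cytokinin (adjusted p = 0.0719), gibberellin and brassinosteroid (0.0835) and defence (0.0646) sets did not pass. The cytokinin set did not pass with slide as a block (median -0.29, adjusted p = 0.247) or without ore15-2 replicate 2 (0.0669), nor the gibberellin and brassinosteroid set without ore15-1D replicate 1 (0.0585) or ore15-2 replicate 2 (0.0551).

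The other lists did not pass as sets between the mutants, with camera adjusted p from 0.158 to 0.898. The trichome list passed without a filter on background (median 0.60, adjusted p = 0.0407), the auxin list after normexp with the local background (-0.41, adjusted p = 0.0228), and the root (adjusted p = 0.0107) and PLATZ (adjusted p = 0.0349) lists with fry. Of 22 clock genes 5 were higher and 7 lower in ore15-1D, also adjusted over the list alone, with PRR5 at 1.81 ± 0.23, CCR2 at 1.98 ± 0.37, LHY at -1.56 ± 0.33 and RVE1 at -1.57 ± 0.28. Of 9 trichome genes 6 were higher and 1 lower, also adjusted over the list alone, and the one lower was TRY (-1.76 ± 0.36). SPT (2.44 ± 0.29) and ANT (1.60 ± 0.26) were among 8 leaf size regulators that were higher, with 4 lower (8 and 6 adjusted over the list alone). Auxin response genes were higher in 4 and lower in 8 of 24 cases, also adjusted over the list alone, with IAA29 at -2.52 ± 0.48. The counts higher and lower were 4 and 4 of 13 CDK inhibitor and endocycle genes (5 and 4 adjusted over the list alone), 2 and 4 of 11 polarity genes (3 and 4), 1 and 3 of 16 stomatal genes (1 and 3) and 2 and 4 of 15 cold and abscisic acid genes (2 and 3). They were 1 and 3 of 9 vascular genes (1 and 3), 1 and 4 of 7 PLATZ genes (1 and 4), 1 and 3 of 7 root genes (1 and 3), 2 and 1 of 4 floral genes (2 and 1) and 0 and 1 of 3 meristem genes (0 and 1 by limma). FUL was higher by 2.91 ± 0.12, SEP3 by 2.70 ± 0.23, NRT2.1 at least 20.5-fold lower and CLV1 lower at -0.75 ± 0.12.

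The changes of both mutants against Col were then set against each other across genes. Some genes changed in opposite directions. The defensin-like gene AT2G16367 fell by 3.48 (SE 0.38) in ore15-1D and rose by 3.36 ± 0.38 in ore15-2, and the glutathione transferase gene GSTF6 gave -1.97 ± 0.20 and 2.32 ± 0.20. ERF1, an ethylene response factor gene, was at least 3.03-fold lower in ore15-1D and rose by 2.14 ± 0.27 in ore15-2. The subtilase gene AT4G21650 rose by 1.29 ± 0.10 and fell by 1.18 (SE 0.10), and MIR172a, the locus of a microRNA precursor, rose by 1.35 ± 0.12 in ore15-1D and was at least 1.56-fold lower in ore15-2. Other genes changed the same way in both, such as ASG4, a MYB-related gene (1.99 ± 0.27 and 2.15 ± 0.27), AT4G33467, MIOX2, ELF4, LUX and PRR5.

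Of the genes tested in both, 415 changed in both mutants, 184 of them in opposite directions. There were 128 lower in ore15-1D and higher in ore15-2, against 96.5 for independent lists, and 56 higher in ore15-1D and lower in ore15-2, against 59.1. There were 148 lower in both, against 70.1, and 83 higher in both, against 81.4. In 20 simulated sets of unchanged groups that shared the Col arrays no gene passed in either by limma, so equally long lists were taken by rank instead, a choice made after the data were seen. Sharing the Col arrays alone then gave on average 34.2 genes lower in ore15-1D and higher in ore15-2, 23.2 the other way round, 234.8 lower in both and 305.6 higher in both. Across 20284 genes, which are not independent replicates, Pearson's r was -0.167 and Spearman's rho -0.267. In 100 simulations of unchanged groups sharing the Col arrays r was 0.498 and rho 0.444, and the covariance was -0.0678 against a simulated 0.0406, a difference of -0.108. Neither these simulations nor the ranked lists held a changed gene, whereas 40.6% of genes changed in ore15-1D. The overlap and r that come from sharing the Col arrays can thus differ in the data from the simulated values. No slide effect was simulated either. Each mutant lay on a single slide and Col on both, so a slide effect would move the mutants' changes in opposite directions. The simulations therefore do not tell opposite changes of the alleles apart from a slide effect. Part of the overlap in one direction may come from sharing the Col arrays, and a split of them leaves a single Col array for each mutant. With each mutant set against the Col array of its own slide r was -0.0877 and rho -0.172, and without Col replicate 1 r was 0.0227, without Col replicate 2 -0.0705 and without ore15-2 replicate 2 -0.0602. After normexp with the local background and the 75th percentile r was 0.610. That setting was upset by local background values of up to 140221 on Col replicate 1, which both changes share. After normexp with quantile normalization r was -0.163, and without a filter on background it was -0.0216.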

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

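Among the tests below, those of the harvest time, of shoot apex tissue and of both explanations for the difference between the Col arrays were chosen only after the result was seen, and so were the readings of the shoot apex and leaf stage tests. From here on, the SE of a list median is not that of the limma fit, which is kept for single genes. It was taken from the spread of the list's median between arrays of a genotype, pooled over the genotypes. Against a single Col array it assumes that this array varies like the others. With so few arrays, a distance counted in these SEs is a rough guide and no fixed level of confidence.

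Probes with no matched locus were kept out of the comparisons, and signal above Col was found there. Of 2841 such probes tested, 268 were higher and 526 lower in ore15-1D than in Col, and 29 were higher and 18 lower in ore15-2. No gene is named for them here.

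Clock genes in ore15-2 moved toward dawn genes and away from evening genes, and this could come from the slide, from the time of harvest or from the clock itself. Against Col replicate 2, on the slide of ore15-2, the median change of 19 clock genes, counted as positive toward dawn, was 1.06 (SE 0.21), which a slide effect alone does not give. A further 16 dawn and evening genes outside the list shifted by 0.83 (SE 0.20) the same way, as a hypothesis of a clock that stands at an earlier point of its cycle, and so runs late, in ore15-2 needs. The labels give harvest at 5 h after light-on for all samples, but an earlier harvest of the ore15-2 leaves against that hour would predict the same shift as a changed clock, and as the ore15-2 arrays gave 0.99 and 1.35 these cannot be told apart by expression. In ore15-1D the clock list shifted by 0.64 (SE 0.17) and the further genes by -0.11 (SE 0.20), and the difference between the mutants was not tested.

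In ore15-1D, lists of proliferation genes were higher and photosynthesis genes lower by camera with its preset correlation, though not with an estimated one (adjusted p = 0.562 for each). The slide, the scaling or other tissue could account for this pattern. Against Col replicate 1 of the same slide the photosynthesis list lay at -0.67 (SE 0.13), which argues against the slide as the whole cause. With quantile normalization it lay at -0.20 (SE 0.04), still below 0 by more than 2 SE, which counts against the scaling as the whole cause for that choice of scaling only. The size depends on the scaling, and after normexp with the local background the list lay at -0.26 and did not pass (camera, adjusted p = 0.214). The slide and scaling tests used the photosynthesis list alone. The proliferation lists lay between 0.63 and 1.04 above the single Col array of the same slide, for which no SE was taken. After quantile normalization they too passed by camera with its preset correlation. Of 10 shoot apex markers 0 were well above background and higher in ore15-1D, but 3 were measured, and markers near the floor exclude nothing, so apex tissue stays open. A younger stage of the ore15-1D leaves at harvest was not tested and may be the biological alternative.

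The changes in ore15-2 lay partly along the difference between the Col arrays, as across genes they had a correlation of 0.289 with Col replicate 2 minus Col replicate 1, and those in ore15-1D one of -0.296. A slide effect predicts these signs, but so does a difference between the Col samples along which the mutants also differ, such as leaf stage, and these cannot be told apart with 1 Col array per slide. In Col replicate 2 against Col replicate 1 the mitosis list lay at -0.40, with 0% of 10000 random lists matched on expression as low, as a difference in leaf stage was set to need, but such lists lack the correlation of 0.965 estimated between its members, so that this decides nothing. The GRF and GIF list lay at -0.37, histones at -0.088, DNA replication at 0.058 and ribosome biogenesis at 0.38, and with 1 array each leaf stage is neither borne out nor excluded. No biological explanation from the genotypes was tested for this pattern.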

How the results depend on the processing

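Normexp without the local background was chosen after seeing the data. The planned normexp with the 75th percentile was upset by local background values of up to 140221 on Col replicate 1 and 1687 on ore15-1D replicate 2, against 73 or less elsewhere. It gave 0 genes by limma in all 3 comparisons (2255, 725 and 2829 at an unadjusted p below 0.05), 0 loci around ORE15, an ORE15 change of 4.299 in ore15-1D and 6.09 between the mutants, 7 gene lists in ore15-2 and a correlation of 0.610 between the mutants. Under it these values took another sign: in ore15-1D ASG4 -0.40, AT1G31010 -0.085, CLE40 -0.24, COPT3 -0.62, CYCB2;3 -0.24, ENDO3 -0.089, GL3 -1.15, GRF8 -1.24, MIR172a -0.94 and SEP3 -0.54; in ore15-2 ASG4 -0.41, AT2G15555 -0.076, AT5G18037 -0.64, ERF1 -0.52, PI -0.58, RGP3 -0.84 and RVE8 -1.05. In ore15-2 the histone (-0.085) and ribosome biogenesis (0.013) lists lost their direction by camera. The auxin response list there had a median of -0.36, against 0.29 with the planned scaling, and did not pass (camera, adjusted p = 0.887). Normexp with quantile normalization gave 1199 genes in ore15-2, and normexp without the local background 1224. Signs were compared, here and above, only for genes and lists that passed in the main fit or under the alternative. Of the named genes compared in this way, none took another sign under quantile normalization, the mean of probes, the fixed blocks or any left-out array. The photosynthesis list in ore15-2 did under quantile normalization (-0.013).

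With slide as a block 3885 genes passed in ore15-1D, 1 in ore15-2 and 0 between the mutants by limma (7508 unadjusted), with 3 loci around ORE15 and ORE15 at 10.22 between the mutants. Of the named genes, 72 in ore15-1D kept their side of the threshold and 26 did not, against 15 and 51 in ore15-2 and 0 and 29 between the mutants. The 15 in ore15-2 passed in neither fit, so no named call in ore15-2 held. For the 756 genes of ore15-2 the median SE was 0.108 with all arrays, 0.127 with the block and 0.122 in the arrays alone, and 3 residual degrees of freedom fell to 2. These genes were chosen for passing with all arrays, which favours a low SE there, so the values do not show what ended the calls. The median absolute change of these genes was 0.98 with all arrays and with the block, and is the same by construction in the arrays alone. In ore15-2 limma gave 0 genes in the genotypes' arrays alone (3372 unadjusted), 0 without a filter on background (4349) and 1154 with a trend in the spread. Without that filter 2 loci around ORE15 passed and the correlation was -0.0216. A minimum log2 change of 1 left 2446, 363 and 4333 genes. With an estimated correlation 0 lists passed by camera in each comparison (1 unadjusted in each), and with fry 2 did in ore15-2. Apart from the planned normexp, the cause was not tested.

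The replicate numbers do not pair the arrays, as deviations of same-numbered arrays correlated at -0.0899, 0.132 and -0.011. With the replicate number as a block 6540 genes passed in ore15-1D, 3 in ore15-2 and 10089 between the mutants, and 3 loci around ORE15, while the cytokinin list passed in ore15-2 (0.44, adjusted p = 0.0191).

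Leaving out each array gave 815 to 8671 genes in ore15-1D, 0 to 1341 in ore15-2 and 4769 to 11421 between the mutants, a lone array being assumed to vary like the others. The correlation ranged from -0.232 to 0.0227, loci around ORE15 from 0 to 5, and ORE15 from 7.49 to 7.60, from -3.59 to -1.53 and from 9.08 to 11.14, where -3.59 and 11.14 rest on ore15-2 replicate 2 alone, whose probe was not well above background, and are not measured levels. Lists that passed ranged from 14 to 15, 6 to 11 and 13 to 15. Signal over background limits the dim genes, as 67.8% to 73.0% of probes were well above it.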

Other observations

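The test of low-sugar genes against the Col array of the same slide was chosen after the result was seen. Genes that rise under low sugar in leaves were lower in both mutants than in Col in part. SEN5 (AT3G15450) fell by 0.97 (SE 0.26) in ore15-1D and by 2.11 (SE 0.26) in ore15-2, and DRM1 (AT1G28330), a dormancy-associated gene, by 1.00 (SE 0.20) and by 1.67 (SE 0.20). BGAL4, a beta-galactosidase gene, fell by 2.95 (SE 0.21) in ore15-1D and gave -1.08 (SE 0.21) in ore15-2, which did not pass (limma, adjusted p = 0.0736). KMD1 (AT1G80440), which targets type-B response regulators, fell by 2.56 (SE 0.33) in ore15-1D and gave -0.74 (SE 0.33) in ore15-2. In all 10 of 14 such genes fell in ore15-1D and 2 in ore15-2.

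A hypothesis of a lower low-sugar response in both mutants was set against these 14 genes, which lie outside the senescence list. Their median was -0.82 (SE 0.15) in ore15-1D and -0.29 (SE 0.15) in ore15-2, the latter less than 2 SE below 0, so that the test leaves it open for ore15-2. Against the Col array of its own slide the median was -0.69 (SE 0.19) in ore15-1D and -0.46 (SE 0.19) in ore15-2, each more than 2 SE below 0 and without a shared Col array. Each of these rests on 1 Col array and was chosen after the result was seen, so the hypothesis stays open for ore15-2.

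Further genes of the evening and dawn were named after their values were seen. COR28 (AT4G33980), an evening gene, fell by 2.07 (SE 0.23) in ore15-1D and by 2.57 (SE 0.23) in ore15-2, and CDF2 rose by 0.90 ± 0.15 and 1.17 ± 0.15. In ore15-2 LNK3 (AT3G12320) rose by 1.62 ± 0.23 and CCR1 fell by 1.52 (SE 0.23).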
